A study of Homo sapiens with 4 samples.

How the data were processed

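Total RNA of 2 lung cancer cell lines, 95C with low and 95D with high metastatic capacity per the labels, was amplified with random primers, labelled with Cy3 and hybridised to a 1-colour Arraystar lncRNA array that carries probes for coding transcripts and long non-coding RNAs (lncRNAs). There were 4 scanner files, 2 per line, and a pair of tables of processed values. Per the file headers, the images were read with Feature Extraction 11.0.1.1 under the protocol GE1_1100_Jul11, and the array design refers to the genome build hg19. The signals in the scanner files are intensity values on a linear scale which, per the file headers, are the software's processed signals, with its background correction already applied. The authors also deposited log2 values in a table for 21718 coding probes and a table for 11492 lncRNA probes, with 0 probes in both. The coding table held a further 3605 rows without a probe number, which were not used. How the authors made these values is not given in the sources used here. Set against the scanner files, they followed quantile-normalized log2 processed signals, with an offset of 0.08 in the median and a correlation of 0.998 across probes for the difference between the lines. These deposited log2 values were used as an alternative and to tell coding from lncRNA probes. Of the deposited probes, 0 were well above background on no scan, so both classes lacked probes dim on every scan from the start.

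Each scan held 61184 spots, of which 58945 were single-spot probes of the array and the rest were controls. Between 41272 and 42529 of the 58945 probes were well above background on a scan, or 70.0% to 72.2%, and the 75th percentile of the signal lay between 206.0 and 218 intensity units. A spot was saturated in 0 cases. The number of arrays limits the precision.

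The files of one line turned out to be repeat scans of one hybridised array. The headers gave the same array position to both files of a line, scanned 2 days apart, and both lines were in one scan image on each occasion. Of the 158 and 161 spots with a non-uniform local background on the 95C scans, 152 were the same spots, where 0.416 would be shared by chance. The 95D scans shared 8 of 16 and 15, and 0 such spots were shared between the lines. Deviations of replicated control spots from their probe's median correlated at 0.877 and 0.880 between the scans of a line and at 0.459 to 0.514 between lines, across spots that are not independent samples. The scans were therefore averaged and each line counted as 1 replicate. The planned limma test (adjusted p under 0.05) was not used, because repeat scans carry no error between cultures, extracts or hybridisations. No p-value across probes was computed, and the difference between the lines has no replicate check. In its place stands a rule of size, chosen after the repeat scans were found: a probe was counted when its mean differed by at least 2-fold.

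Signals were scaled as log2 of the processed signal minus the scan's 75th percentile over all 58945 probes. A probe was tested when it was well above background on both scans of at least 1 line. Probes that the scanner software marked as an outlier in spot or local background, on either scan of either line, were left out, as planned, and saturated spots would have been kept. Which of the software's marks counted was settled after the data were seen. This left 20199 coding and 10669 lncRNA probes. Differences are 95D minus 95C. A probe well above background in 1 line and on neither scan of the other has only a bound, the bright line's mean against, per scan, the higher of the probe's own signal and the lowest signal well above background.

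The files give a probe number and no gene name, and the gene tables at hand hold no such numbers, so 0 probes were named. The gene lists and the rule for named genes, like the scaling, the filter and the alternatives listed first, were fixed before the data were examined, and both need gene symbols, so they could not be applied. In their place 4 probe numbers are given, a rule set after the values were seen: in each class and direction, the largest difference among probes well above background on all 4 scans, with no adjacent probe at least 2-fold different in the same direction. GAPDH, one of the reference genes fixed in advance, was read from control spots that carry its name. PGK1, read the same way, was added after its values were seen. Pairs of an lncRNA and its associated coding gene could not be formed.

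Alternatives were quantile normalization, normexp background correction on the median signals (offset 50 or none, limma 3.58.1 in R 4.3.3, fitted on all spots) followed by quantile normalization, other scaling sets, other filters on dim probes, the deposited values, leaving out each scan, and the scan occasion as a block. The median signals took the place of the mean signals, which the scanner files used here do not list. Spot error was measured on control probes printed at least 10 times, as the difference between the 2 arrays at the same position minus the probe's median difference. Spots the software marked as population outliers were kept in this step, since that mark exists only for replicated probes and dropping them cleans control spots but not tested probes. This was the third estimate of spot error computed, and it and the bounds for reading it were settled after the values of the earlier ones were seen. The first dropped population outliers and the second kept them, and both set any 95C spot of a probe against any 95D spot. The bounds written at the start were for the first estimate. Adjacent spots were those within 14 position units, and chance was set by 1000 shuffles of the differences among probes of similar signal. The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated data: of 50 probes each seeded 3-fold, 4-fold and 8-fold apart, 100% were counted, and of 50 seeded 1.5-fold apart, 0%, in a simulation of 58945 probes for 95D against 95C with spot error. Of 58652 unchanged probes 0% were counted. The simulated log2 difference of unchanged probes had an SD of 0.15, below the 0.47 of control spots with a signal at or below 0, so the simulation tests the steps and does not measure how often spot error passes 2-fold. It also held a patch of shifted probes, of which 100% of 93 had a like neighbour, against 1.33% of 150 seeded probes outside it.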

Results

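Expression of coding and long non-coding transcripts was compared between 95C and 95D, a pair of human lung cancer cell lines described as low and high in metastatic capacity. The question was which lncRNAs differ between lines of different metastatic capacity. Each line was represented by 1 hybridised array, scanned on 2 occasions, so that values below are means of 2 scans and any SD between scans is that of reading the same array again. The differences between the lines have no replicate check and no p-value is given. The files do not pair probe numbers with genes, so probes are described by class, and only the GAPDH and PGK1 control probes carry gene names.

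The 2 lines had similar profiles. Scaled log2 signals correlated at 0.988 across 20199 coding probes and at 0.979 across 10669 lncRNA probes, which are not independent replicates. The difference between the lines was below 1.5-fold for 88.9% of coding probes and 89.7% of lncRNA probes. Its median was 0.04 for coding and 0.01 for lncRNA probes on the log2 scale, and the middle 90% of differences ran from -0.60 to 0.62 and from -0.56 to 0.62. Among all array probes well above background on both scans, in a table or not and with marked outliers kept, the SD of the log2 difference was 0.157 between the 95C scans and 0.134 between the 95D scans, and 0.436 to 0.452 between a 95C and a 95D scan. Estimated from the median absolute deviation, which outliers move little, it was 0.07 between the scans of either line and 0.28 to 0.29 between lines. The values between scans of 1 line hold the error of reading an array again and not that between arrays. Differences of control spots between the arrays, less their probe's median difference, had an SD of 0.366, or 0.466 at a mean scaled signal at or below 0. This is scatter of spots within a probe. It leaves out any shift shared by all spots of a probe, so the whole error between arrays was not measured. Second scans were dimmer than first scans by a median of -4.73% for 95C and -4.53% for 95D before scaling.

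For coding transcripts, 278 probes were at least 2-fold higher in 95D and 330 at least 2-fold lower, together 3.01% of those tested. At least 4-fold differences were seen for 60 and 59 probes, of which 28 and 25 were well above background on all scans, and at least 8-fold differences for 19 and 23, of which 6 and 10 were. The others were set against a signal not well above background on at least 1 scan, so their fold is uncertain. On each scan occasion taken alone, 230 of the higher and 268 of the lower probes passed 2-fold. Probe ASHGA5P053888 was 75.1-fold lower in 95D, with a log2 difference of -6.15 on the first and -6.32 on the second occasion. Its processed signal was 3070 intensity units in 95C and 41.4 in 95D, and the 4 tested probes adjacent to it differed by -0.21 to 0.30. After normexp correction and quantile normalization it differed by -4.43, and by -5.06 without the offset. Probe ASHGA5P010996 was 15.8-fold higher in 95D, with log2 differences of 3.90 and 4.06 on the 2 occasions and processed signals of 35.5 in 95C and 566 in 95D. Its 4 tested neighbours differed by -0.07 to 0.16, and after normexp correction and quantile normalization it differed by 2.23, or 2.86 without the offset. With the scans' 75th percentile as the lower bound on mean signal, 62 coding probes were at least 2-fold higher and 48 at least 2-fold lower, of 8780. After normexp correction and quantile normalization in place of the processed signals, the counts over all tested probes were 38 and 45. Among probes well above background on all scans, 193 were higher and 217 lower.

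For lncRNAs, 199 probes were at least 2-fold higher in 95D and 164 at least 2-fold lower, together 3.40% of those tested. Differences of at least 4-fold were seen for 52 and 42 probes, of which 16 and 7 were well above background on all scans, and of at least 8-fold for 12 in each direction, of which 1 in each direction was. The fold of the others is uncertain, as for coding probes. On each scan occasion taken alone, 163 and 129 of them passed 2-fold. Probe ASHGA5P044934 was 5.91-fold higher in 95D, with log2 differences of 2.46 and 2.67 on the 2 occasions and processed signals of 18.2 in 95C and 109 in 95D. Its 6 tested neighbours differed by -0.12 to 0.80, with a median of 0.29, in the same direction. Probe ASHGA5P018161 was 5.23-fold lower, with log2 differences of -2.39 and -2.38 and processed signals of 88.1 and 17.1. Its 3 tested neighbours differed by -0.46 to 0.56, with a median of -0.00. After normexp correction and quantile normalization ASHGA5P044934 and ASHGA5P018161 differed by 0.76 and -0.74, and by 1.27 and -1.32 without the offset. Larger differences, of 3.07 and -3.06 among lncRNA probes well above background on all scans, lay beside probes that differed in the same direction. With the 75th percentile as the lower bound on mean signal, 14 lncRNA probes were at least 2-fold higher and 10 at least 2-fold lower, of 2441. Among probes well above background on all scans the counts were 109 and 80, after normexp correction and quantile normalization 11 and 15, and without probes that have an adjacent probe differing in the same direction 132 and 107.

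**Figure D1:**
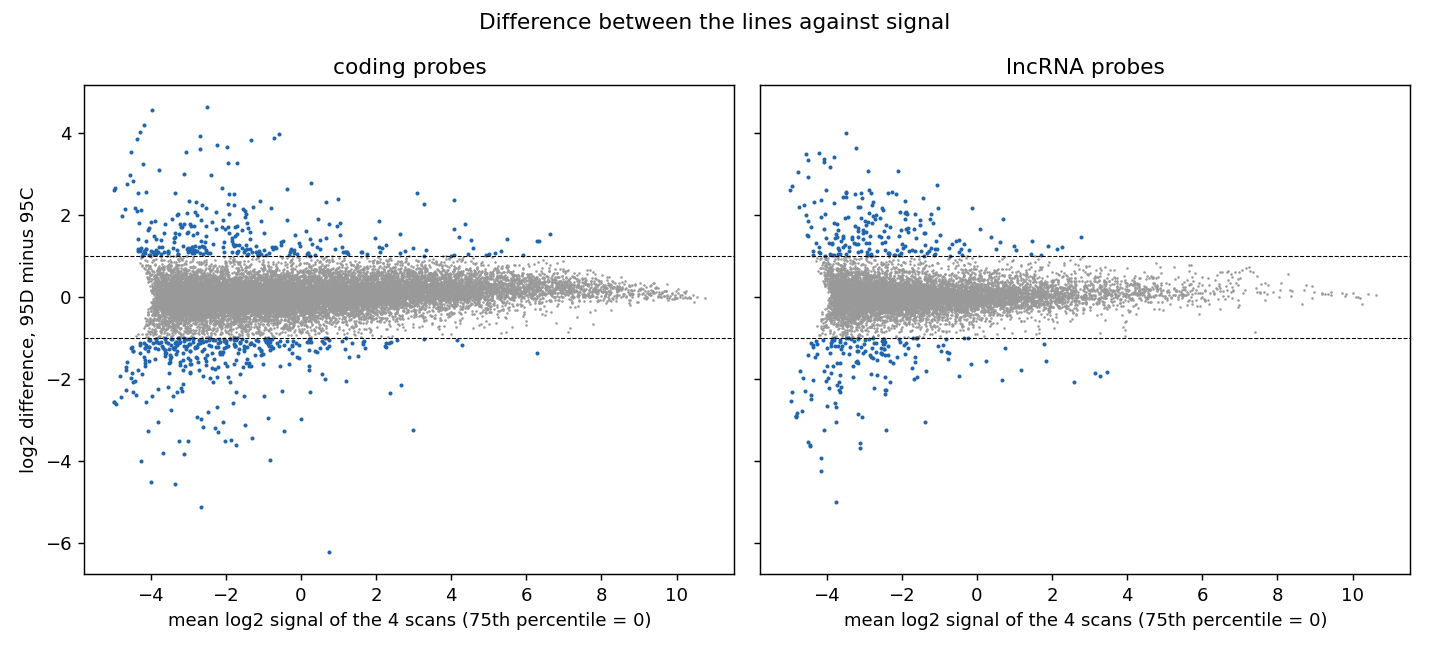
Log2 difference between the lines (95D minus 95C) against the mean scaled log2 signal of the 4 scans, for tested coding probes (left) and lncRNA probes (right). Blue points are at least 2-fold different, which holds for 608 coding and 363 lncRNA probes, most of them left of 0 on the signal axis.

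Some transcripts were well above background in 1 line and on neither scan of the other. In 95D these were 129 coding and 146 lncRNA probes, of which 23 and 28 were at least 2-fold higher than the bound for 95C. In 95C they were 190 coding and 141 lncRNA probes, of which 35 and 27 were at least 2-fold above the bound for 95D. The largest bounds for coding probes were at least 13.6-fold in favour of 95D and at least 14.4-fold in favour of 95C, and for lncRNA probes at least 5.97-fold and at least 8.91-fold. Of the 23 and 35 coding probes, 10 and 16 lay beside a probe that differed in the same direction, as did 14 of the 28 and 12 of the 27 lncRNA probes.

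The share of probes at least 2-fold different fell with signal, from 7.78% of the 4732 probes with a mean scaled log2 signal below -3 to 0.896% of the 5689 above 2. The median difference went from -0.02 below -3 to 0.15 above 2, where 34 probes were at least 2-fold higher and 17 lower. Bright probes were thus not centred on 0, and higher ones passed the threshold more easily than lower ones. LncRNA probes were dimmer than coding probes, with a median processed signal of 63.4 against 150 intensity units in 95C and of 64.3 against 152 in 95D. Their share of 2-fold differences was 0.39 percentage points above that of coding probes, while among probes well above background on all scans the shares were 1.92% for lncRNA and 2.12% for coding probes. Weighted to the same distribution of signal over 20 ranges, the shares were 2.77% for lncRNA and 3.38% for coding probes, a difference of -0.61 percentage points, outside the -0.42 to 0.40 that held 95% of 1000 shuffles of the differences within ranges. The matched difference was -0.02 under normexp and quantile normalization, turned to 0.02 without the offset, and was -0.02 for 4-fold and -2.42 for 1.5-fold differences. As a ratio, the lncRNA share was 0.820 times the coding share, 0.943 and 1.02 times under normexp with and without the offset, 0.968 times at 4-fold and 0.794 times at 1.5-fold. The shuffles describe these 2 arrays and are no replicate error.

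Control probes printed at least 10 times showed how far the difference of a spot between the arrays strays from the median difference of its probe. A shift shared by all spots of a probe is taken out and does not count here. Of 745 control spots of 55 probes, 15 differed from their probe's median by at least 2-fold. All 15 were among the 451 spots with a mean scaled signal at or below 0, a share of 3.33% (95% exact binomial interval 1.87% to 5.43%, which covers counting error only), where 4.26% of the 19647 tested probes were at least 2-fold different. Above 0 the count was 0 of 294 control spots, with an upper limit of 1.25% by the same interval and a largest deviation of 0.47 on the log2 scale. There, 134 of 11221 probes were at least 2-fold different, or 1.19%. The shares at low signal depended on how spot error was estimated: below -3 they were 0.978% and 17.4% under 2 earlier estimates, against 2.52% here.

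**Figure D2:**
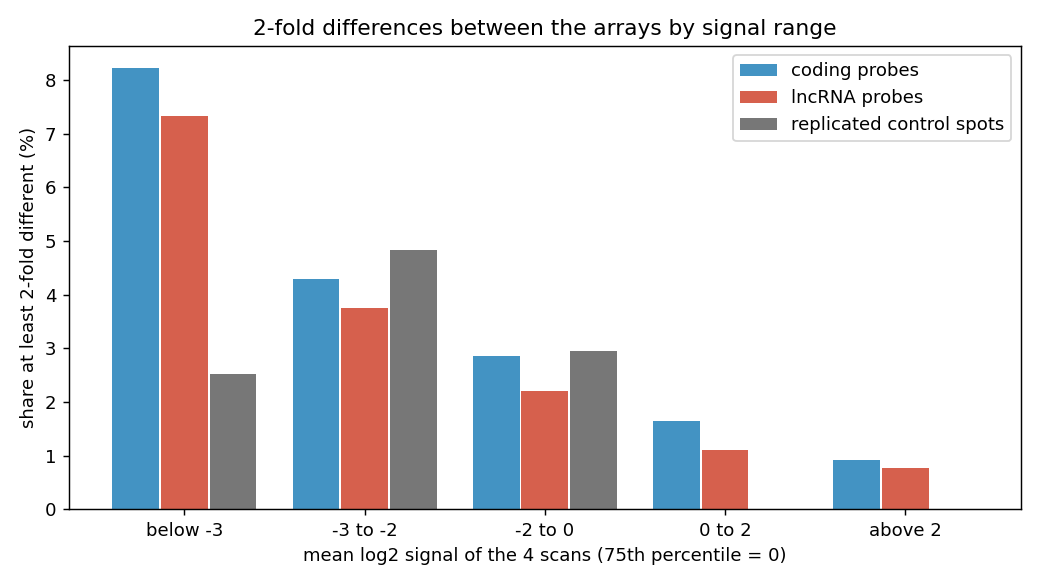
Share of coding probes, lncRNA probes and replicated control spots at least 2-fold different between the 2 arrays, in 5 ranges of the mean scaled log2 signal. Control spots, taken as deviations from their probe's median, gave 2.52% below -3, 4.83% from -3 to -2, 2.94% from -2 to 0, and 0% in both ranges above 0.

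GAPDH and PGK1, both genes of glycolysis, are printed as control probes of 10 spots each, and all spots of the 4 human probes were well above background and unsaturated. The probe Human-GAPDH_3 differed by -0.00 between the lines (10.03 ± 0.04 in 95C, 10.03 ± 0.03 in 95D, SD over 8 and 9 spots of 1 array each), within 0.05 of 0 under the other scalings. Human-GAPDH_5 was lower in 95D by a log2 difference of -0.30 (9.84 ± 0.09 over 9 spots in 95C, 9.54 ± 0.04 over 10 spots in 95D). Human-PGK1_3 differed by 0.13 (10.23 ± 0.05 over 10 spots, 10.36 ± 0.03 over 9) and Human-PGK1_5 by -0.16 (6.17 ± 0.05 over 9 spots in 95C, SD 0.06 over 10 spots in 95D). The direction of the last 3 held under median centring, the other scaling set and quantile normalization, under which Human-PGK1_5 differed by -0.31. The 2962 tested probes with a mean scaled signal above 4 had a median difference of 0.18. Relative to it Human-PGK1_3 differed by -0.05, a turn in direction, and Human-GAPDH_3 by -0.18. The turn depended on this set, which reaches down to signals well below those of these 2 probes. The 98 tested probes about as bright as Human-GAPDH_5 had a median difference of 0.0485. The 0.13 of Human-PGK1_3 lay above that median and the -0.00 of Human-GAPDH_3 below it. None of the 20 further replicated probes with design numbers alone was 2-fold different, with differences from -0.14 to 0.44.

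**Figure D3:**
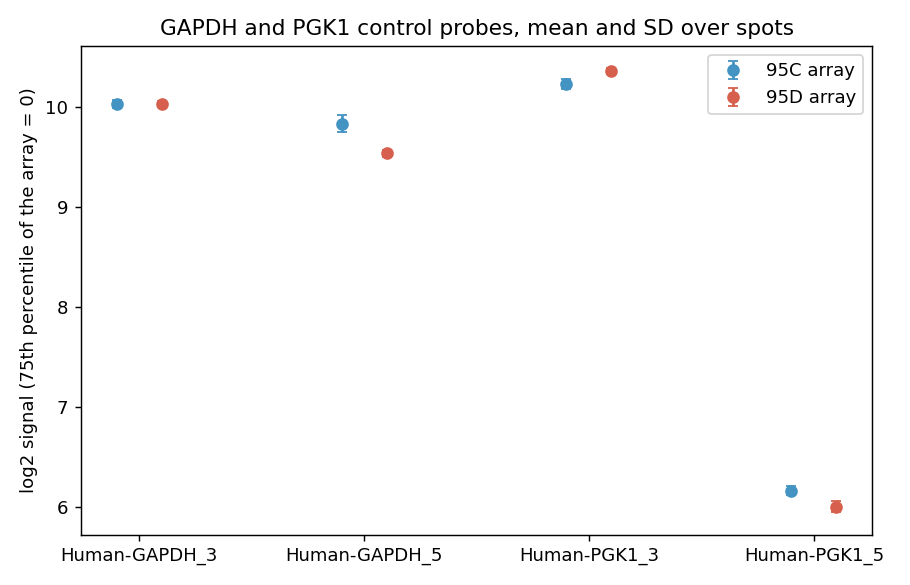
Scaled log2 signal of the GAPDH and PGK1 control probes on the 95C and 95D arrays (points, mean over spots; bars, SD over spots of 1 array). Human-GAPDH_5 lies lower on the 95D array (9.54 against 9.84), while Human-GAPDH_3 lies at 10.03 on both.

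The 95C array carried a contiguous block of disturbed background. In the 95C scans 167 spots, in rows 97 to 125 and columns 80 to 87, had a non-uniform local background on at least 1 occasion, against 23 spots in the 95D scans. With no spots left out, 201 probes of any class were at least 8-fold lower in 95D, and 51 of them, or 25.4%, lay on or within 1 spot of this block, against 0.418% of all probes tested. Of the 37 probes at least 256-fold lower, 35 did. Of the 124 probes at least 8-fold higher in 95D, 0 lay at the disturbed spots of the 95D array.

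**Figure D4:**
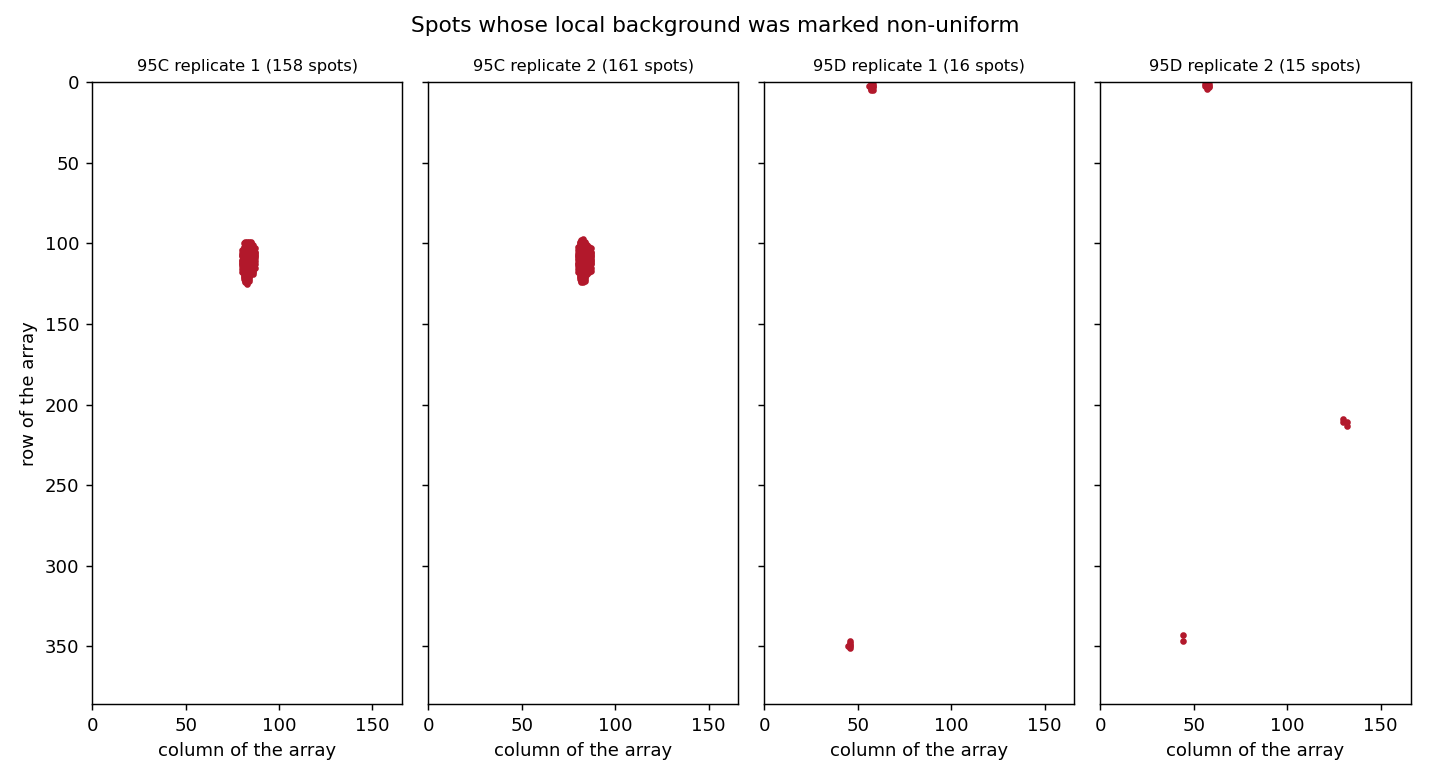
Position by row and column of the spots with a non-uniform local background on each of the 4 scans. The 158 and 161 spots of the 95C scans form the same block, and the 16 and 15 of the 95D scans lie elsewhere.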

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

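The tests of local unevenness and of spot error in this part were chosen after the result was seen.

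Probes in neither deposited table gave signal as well. Of 25735 such probes, 7868 were well above background on all scans and not marked as outliers, and 693 were at least 2-fold different, 336 higher and 357 lower in 95D, or 7.61% of the 9101 tested. Among the 7868 the counts were 79 and 54, or 1.69%, and 329 of the 693 had an adjacent probe at least 2-fold different in the same direction. The class of the probes in neither table was not determined here. Whether some of them belong to the 3605 coding rows without a probe number is not known.

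Over all tested probes, in a table or not, 37.9% of the 1664 had an adjacent probe at least 2-fold different in the same direction, against a mean of 8.14% and a highest value of 11.1% over 1000 shuffles among probes of similar signal, while signal levels of adjacent probes did not correlate (r = -0.00 across 79512 pairs), so local unevenness of 1 array may account for part of them. Of the 971 coding and lncRNA probes, 31.1% had such a neighbour or a shifted neighbourhood. This argues against unevenness that shifts adjacent spots alike on the log2 scale as the whole cause. It cannot exclude unevenness confined to 1 spot or too weak to move brighter neighbours, and only tested probes were searched as neighbours. Spot error stays open: at the control spots' rate in each range of signal, 662 of the 971 would be expected, or 68.2%, with a bootstrap interval over control probes of 27.5% to 160%, so it cannot be told apart from a difference between the lines for most dim probes. Above the 75th percentile of signal, 17 of the 134 probes had a like neighbour and 0 of 294 control spots passed 2-fold. The upper limit for these control spots, 1.25%, was above the 1.19% of tested probes, so spot error is not excluded there either. A difference in expression between lines of low and high metastatic capacity also stays open and untested, since each line had 1 array.

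The choice of estimate of spot error matters more than its bootstrap interval shows: 2 earlier estimates gave 5.46% and 179% in place of 68.2%. The first of them, at most 0.126 times the share of tested probes in any range of signal, met the bound of 0.5 written beforehand for arguing against spot error, and was given up because it dropped population outliers, a mark that only replicated probes can get. It also took only control probes with all spots well above background in at least 1 line. The gap between the estimates can therefore not be put down to that mark alone.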

How the results depend on the processing

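The settings without offset, other fold thresholds, marks of outliers, single occasions, neighbours, loess, floor and bright probes were added after the data were seen. The replicate block, here the scan occasion shared by same-numbered scans, gave 278 and 330 coding and 199 and 164 lncRNA probes higher and lower, the unblocked counts, since a balanced mean does not move. Deviations of same-numbered scans correlated at 0.03 across 39305 probes. Without 1 scan, counts ran from 266 to 311 and 334 to 361 for coding and from 196 to 222 and 163 to 174 for lncRNA probes, within 1.5 times the values above, as were those under quantile normalization, other scaling sets, the deposited values (919 of 971 probes shared) and no filter on dim probes. Dropping that filter could hardly move the counts. It raised the tested probes only to 20465 coding and 10868 lncRNA, since the deposited tables hold no probe dim on every scan. The 15285 dim probes in neither table have no class and could not enter. Normexp and quantile normalization gave 38 and 45 coding and 11 and 15 lncRNA probes, and 77, 86, 51 and 35 without the offset of 50. The offset thus accounts for part of the fall, and the cause of the rest was not tested. Probes well above background on all scans, 19378 of 20199 coding and 9856 of 10669 lncRNA probes, gave 193 and 217 coding and 109 and 80 lncRNA probes. Those left out had needed to be well above background in 1 line only, a filter that can favour differences. Probes above the 75th percentile, 8780 coding and 2441 lncRNA probes, gave 62, 48, 14 and 10. At 1.5-fold the counts were 1165, 1074, 614 and 487, at 4-fold 60, 59, 52 and 42. Without like neighbours, lncRNA counts were 132 and 107. The share of lncRNA minus coding at matched signal turned to 0.0157 percentage points under normexp without offset. It was -0.0213 with the offset, -0.0219 at 4-fold, -2.42 at 1.5-fold and -0.387 above the 75th percentile. Human-PGK1_3 turned to -0.0460 relative to the median of probes with a mean scaled signal above 4. Its 0.13 lay above the median of 0.0485 of probes as bright as Human-GAPDH_5. The 4 named probes kept their direction in every setting that gave a value, moving by over 0.160 (1 SD between scans) only under normexp (3.98 to 2.23, -6.23 to -4.43, 2.56 to 0.76 and -2.39 to -0.74). Not run were limma's moderation, adjusted p thresholds and families, means over probes of a gene, gene lists and lncRNA pairs, for want of replicates or gene names. Low signal over background limits most counts.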

Other observations

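The tests of a dye or scanner limit, of RNA integrity and of signal in this part were chosen after the result was seen. That of the spots around GAPDH was chosen before.

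The GAPDH and PGK1 probes parted within each gene: the log2 difference of the _5 probe minus that of the _3 probe was -0.29 for both genes. Uneven hybridisation around the spots is argued against by the probes adjacent to Human-GAPDH_5, whose median difference was -0.0205. A dye or scanner limit that lowered bright signals in 95D is argued against by 98 array probes within 0.5 of the mean level of Human-GAPDH_5. Their median difference was 0.0485 (95% bootstrap interval 0.01 to 0.07), and 0 spots were saturated. A limit that pulls the differences of bright probes toward 0 would also give a median near 0, so this test cannot exclude it. An earlier test on Human-PGK1_5 was dropped because the pattern fixed its outcome. RNA integrity or priming that differed between the 2 extracts may account for the gap in GAPDH (-0.29), if the suffixes stand for ends of the transcript, but cannot be told apart from other causes, since the position of other probes is not known here: Rat-GAPDH_5 (-0.27), Mouse-PGK1_5 (-0.17) and Rat-PGK1_5 (-0.16) were lower and Rat-GAPDH_3 (-0.03) and Mouse-PGK1_3 (-0.04) near 0, but Mouse-GAPDH_3 was lower (-0.24) and Mouse-GAPDH_5 near 0 (-0.05), and Rat-PGK1_3 was not above background. These further probes are named for rat and mouse, and what they bind in human RNA was not tested. Those near 0 were dim, with median signals of 252 to 303 units in 95C and SDs over spots of 0.17 to 0.25. The lower ones had 756 to 65041 units in 95C. The rat and mouse probes therefore cannot decide whether the ends part. A difference between the lines in transcript forms is open and was not tested.

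The larger share of 2-fold differences among lncRNA probes than among coding probes may come from their lower signal. At matched signal the lncRNA share was not larger but differed by -0.61 percentage points. The difference was -2.42 at 1.5-fold, -0.02 after normexp correction and quantile normalization and 0.02 without the offset. Under normexp 38 coding probes were at least 2-fold higher and 45 lower, and 11 and 15 lncRNA probes, so a gap in percentage points shrinks with them. The ratio of the shares moved as well, from 0.820 to 0.943 and, without the offset, 1.02. With so few counted probes and no interval for the ratio, this move cannot show whether fewer counted probes are the whole of it. Whether lncRNAs have a lower share stays open. No biological explanation was tested.

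The share of coding and lncRNA probes at least 2-fold different also varied over the array, from 1.59% to 4.89% in bands of 32 rows, where 1000 shuffles of positions reached at most 4.54% in a band.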
